A study of Mus musculus with 34 samples.

How the data were processed

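RNA of sorted monocytes and macrophages was measured in 34 mouse libraries, prepared per the labels' protocols from 100 ng of TRIzol-extracted RNA with a strand-specific poly(A) kit (KAPA) and 14 cycles of PCR. The authors deposited 1 table of estimated counts per gene for all libraries, with genes given by Entrez Gene ID and no scaling to a common total. The deposited values are expected counts rather than whole counts: 14.62% of the values are not whole, in 7434 of 24475 genes. CASAVA 1.8.2 and the genome build GRCm38 (mm10) were used, per the submitters' processing notes; the aligner and the counting tool are not given in the sources used here. The design had assumed whole counts, and the expected counts were rounded to whole numbers, which changed no library total by more than 0.000368%. Multi-mapped reads divided by the authors' estimate can place counts on near-identical genes, so members of the H2, Ly6c, Apol9 and Ear families are uncertain.

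Columns were matched to samples by the identifier in each sample's description, and groups came from the titles. The tumor field of the MC38 samples counts upward from sample to sample, so the titles were used in its place. Gene symbols and GRCm38 coordinates came from a RefSeq table of assembly GRCm38.p6, matched on Entrez Gene ID for 24375 of 24475 identifiers. The 100 unmatched identifiers held 1.43% of all counts, 1.38% in a single identifier. They were kept in the library sizes and tests and passed over when genes were named.

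Libraries from mice (24 libraries, 6 groups of 4) and cultured libraries (10 libraries) were fitted separately in edgeR 4.0.16 (R 4.3.3), with filterByExpr, TMM scaling, robust dispersion and the quasi-likelihood F-test, which is 2-sided, with Benjamini-Hochberg adjustment at 0.05. This left 13200 genes in vivo (biological coefficient of variation 0.177, scaling factors from 0.845 to 1.18) and 12603 in culture (0.282, factors from 0.937 to 1.09). The 12 comparisons included 2 tests of differences between differences. The SE was |log2 difference| over the square root of F. CPM used TMM library sizes, and log2 CPM a prior count of 2. Where a group had 0 counts the fold was bounded against 3 counts over the group, and where it had 1 to 3 counts a 95% exact counting interval of the ratio was computed. Gene by gene, every pair of replicates differed by more than sampling noise.

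Gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01 and, beside it, with an estimated correlation and with fry, adjusted over the 24 lists tested within a comparison. Camera called 157 of 288 pairs of list and comparison, and 11 of these held with an estimated correlation. Median, mean and test differed in sign in 29 pairs, none of them called. With genes at 0 counts set to their bound, 18 of 288 list medians differed, by at most 2.05. The tests, comparisons, gene lists and alternatives were chosen before the data were examined. Named genes were the 10 largest rises and falls per comparison among called genes with at least 10 CPM in the higher group and no overlap between the groups' libraries, up to 4 members of each list with the smallest adjusted p, any list member in both main comparisons, and 5 genes per direction for the tests of differences. Predicted gene models and the sort markers were passed over by that rule, and which of its genes the text names was chosen after their values were seen. The Y-linked and Xist list, fixed for the sex of the mice, was read as levels only. Marker genes of fat, connective tissue, nervous tissue and epithelium and imprinted growth genes were chosen after foreign transcripts had been seen.

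The steps were tested on simulated counts with 200 changed genes. Between tumor monocytes (13200 genes) 49.3%, 73.1% and 83.3% of genes changed by 1.5-fold, 2-fold and 4-fold were recovered. Of 12957 unchanged genes 6 were called. Between supernatants (12603 genes) the shares were 31.3%, 62.7% and 83.3%, with 6 of 12360 called. For the difference between tumors in the change from spleen they were 34.3%, 68.7% and 75.8%, with 8 of 12957. Camera called a list moved on purpose in each and 0 others. Genes were drawn independently and few changed, so correlated lists and scaling under many changes were untested.

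Alternatives were RLE and upper quartile scaling, no filter and a stricter filter (5 CPM in 3 libraries), DESeq2 1.42.0, a fit of only the groups compared, a fit with the replicate number as a term, and each library left out in turn. Leaving out the 5 libraries with foreign transcripts was added after the data had been seen. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15. Single values of some genes that the rule names are not reported here.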

Results

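The series measured polyadenylated RNA of mouse monocytes and macrophages, separated by fluorescence-activated cell sorting, in 34 libraries. Mice of the C57/Bl6 strain carried tumors of LLC, a Lewis lung carcinoma line, or MC38, a colon adenocarcinoma line. From these mice came 6 groups of 4 libraries. They were Ly6C+ CD88+ Sca1+ monocytes of MC38 tumors (TuMon1), Ly6C+ CD88+ Sca1- monocytes of LLC tumors (TuMon2), macrophages of each tumor, and Ly6C+ monocytes from the spleens of the mice with each tumor. Cultured bone marrow monocytes gave another 3 groups: 4 control libraries, 3 libraries of cells given LLC supernatant and labelled as the TuMon2 phenotype, and 3 of cells given MC38 supernatant and labelled as the TuMon1 phenotype. Library totals lay between 13047724 and 26966603 estimated counts, and between 13475 and 16908 genes had counts in a library. The labels do not state whether replicates were separate animals or cultures, so the p-values cover these samples only. Spread was pooled over a fit's groups. Subset and tumor line coincide in vivo, since TuMon1 came only from MC38 and TuMon2 only from LLC tumors.

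The genes of the sorted antigens came first, as a check of the labels. Ly6a, which encodes Sca1, stood at 1734 ± 50.5 CPM (SD, n = 4) in TuMon1 and at 36.5 ± 4.71 CPM (n = 4) in TuMon2, a log2 difference of 5.57 ± 0.63 (SE; adjusted p = 6.28e-07). In culture Ly6a was at 1510 ± 147.8 CPM (n = 3) after MC38 supernatant, 11.6 ± 0.336 CPM (n = 3) after LLC supernatant and 9.49 ± 1.82 CPM (n = 4) in control cells, and the log2 difference between the supernatants was 7.03 ± 0.16. Macrophages, whose labels name no Sca1 gate, had 820.5 ± 129.8 CPM of Ly6a in MC38 tumors and 140.8 ± 41.9 CPM in LLC tumors. C5ar1, which encodes CD88, was at 378.7 ± 15.4 CPM in TuMon1 and 593.8 ± 5.81 CPM in TuMon2, against 28.1 CPM in MC38 and 36.4 CPM in LLC spleen monocytes. Ly6c2, a gene of the Ly6C antigen that shares reads with its near-identical neighbor Ly6c1 and is uncertain for that reason, was at 2840 CPM in TuMon1 and 920.2 CPM in TuMon2. The cultured cells labelled as Ly6C+ TuMon2 had 13.9 CPM of Ly6c2, which fell by 7.02 on the log2 scale against the 1794 CPM of control cells.

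**Figure D1:**
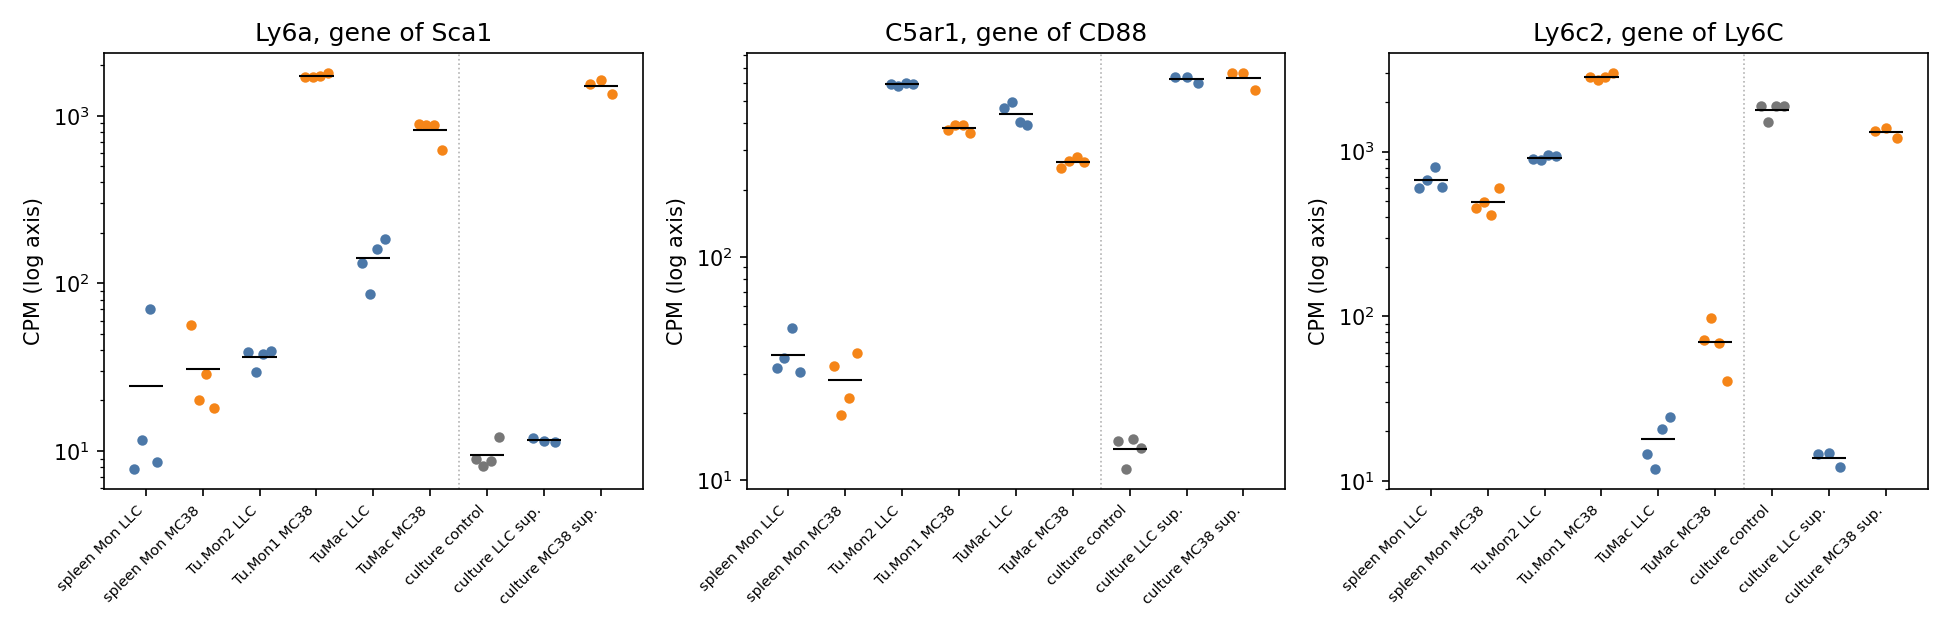
CPM on a log axis of Ly6a, C5ar1 and Ly6c2 in each of the 34 libraries (points), with lines at the group means. Ly6a separates the Sca1+ from the Sca1- groups in tumors (1734 against 36.5 CPM) and in culture (1510 against 11.6 CPM).

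Transcripts foreign to monocytes marked 5 libraries. MC38 spleen monocyte replicates 1, 2 and 3 carried transcripts of fat cells, with Car3 at 3050, 2760 and 5340 CPM and Adipoq at 506, 432 and 801 CPM, where the highest value in any other library was 45.8 for Car3 and 6.32 for Adipoq. MC38 supernatant replicate 3 had 999 CPM of Col1a1, a collagen of connective tissue, and control culture replicate 2 had 78.8 CPM of Actc1, a heart muscle actin. All 5 also held Y-linked transcripts (summed CPM of 24.7, 18.9, 35.3, 11.9 and 31.3), against at most 0.892 in the 29 other libraries, although Xist, the transcript of the inactive X chromosome of females, was present in them. The counts of changed genes are given with and without these foreign-RNA libraries.

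**Figure D2:**
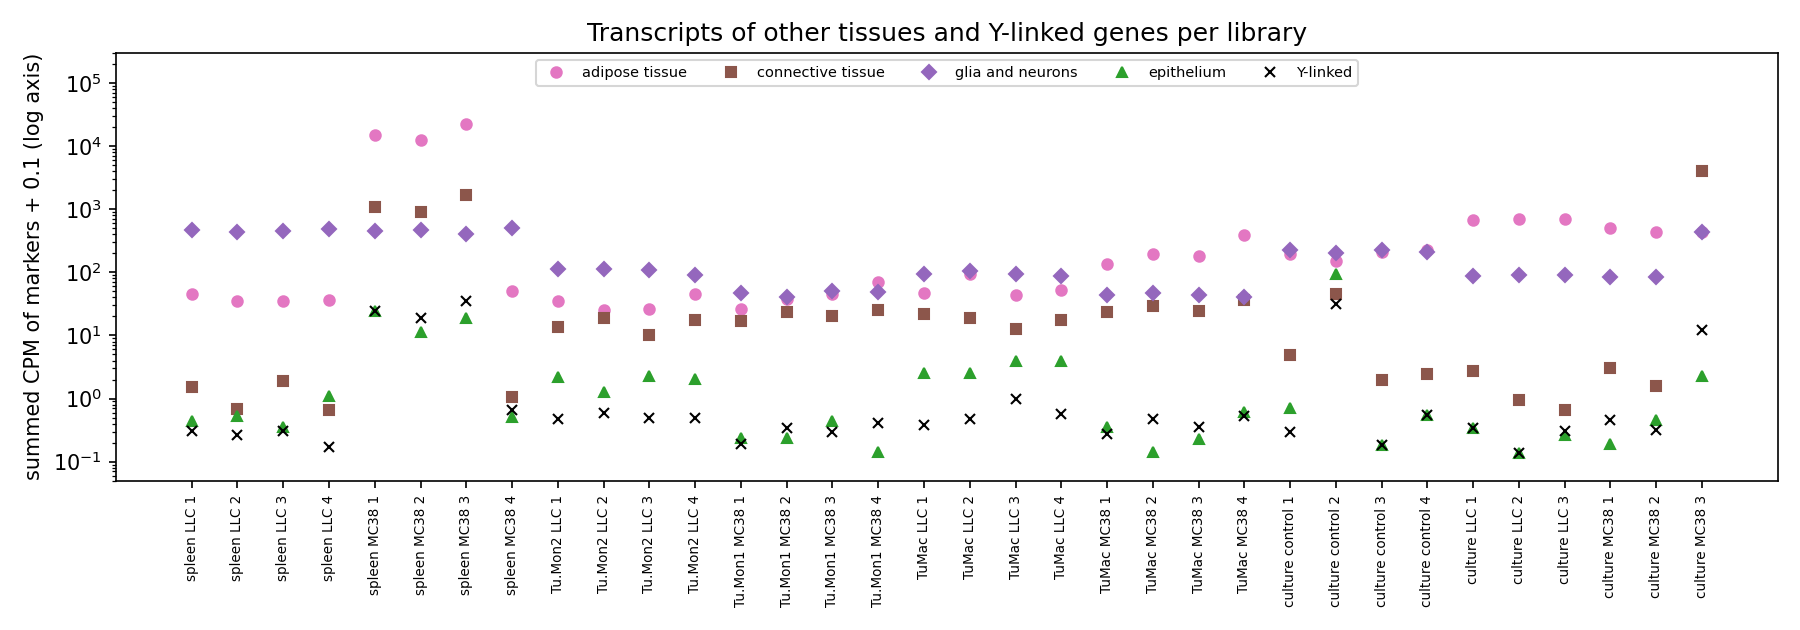
Summed CPM (plus 0.1, log axis) of marker genes of other tissues and of Y-linked genes in each library. The 3 MC38 spleen libraries, control culture replicate 2 and MC38 supernatant replicate 3 carry Y-linked transcripts (11.9 CPM or more), and the 29 others at most 0.892 CPM.

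The Sca1+ monocytes of MC38 tumors (TuMon1) were compared with the Sca1- monocytes of LLC tumors (TuMon2) to find what separates the subsets in vivo. Genes of the interferon response and of antigen presentation were higher in TuMon1, and genes of glycolysis and cholesterol synthesis were higher in TuMon2. Irf7, the transcription factor that amplifies interferon output, stood at 2778 ± 76.9 CPM in TuMon1 and 789.9 ± 42.6 CPM in TuMon2 (SD, n = 4 each; log2 difference 1.81 ± 0.12, adjusted p = 7.83e-12). Fn1, which encodes fibronectin, was at 476.7 ± 51.1 CPM against 11020 ± 1314 CPM (log2 difference -4.53 ± 0.13, adjusted p = 4.86e-18). Sqle, the squalene epoxidase of cholesterol synthesis, was at 11.8 ± 1.09 against 60.7 ± 2.09 CPM (-2.36 ± 0.09, adjusted p = 2.63e-15). Of 13200 genes tested, 3538 were higher and 2911 lower in TuMon1 (54.9% higher, and 48.2% to 58.9% over the alternatives). The majority turned with the stricter filter, without any 1 of the TuMon2 libraries and without TuMon1 replicate 4 (2819 higher, 2835 lower). Changes beyond 2-fold were seen in 1853 genes, and the total of 6449 became 7051 when the spleen libraries with fat cell transcripts were left out of the shared model.

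Among single genes, the largest rises in TuMon1 included Gpr162 (5.74 ± 0.52, log2 with SE), Lipg, endothelial lipase (5.09 ± 0.47), Cd72, a surface lectin (4.90 ± 0.91), and Il2ra, the interleukin 2 receptor alpha chain (4.52 ± 0.40). Cd72 reached 791.8 ± 110.1 CPM in TuMon1 and 26.7 ± 5.26 CPM in TuMon2. The largest falls included those of the eosinophil attractant Ccl24 (-6.19 ± 0.75), the platelet chemokine Ppbp (-5.75 ± 0.46), Fn1 and the neutrophil attractant Cxcl3 (-4.17 ± 0.43). Mmp9, a gelatinase (-3.05), and the matrix proteoglycan gene Vcan (-3.03) were also lower. H2-Q8 had no count in any TuMon2 library and was at least 2250-fold higher in TuMon1, against a floor of 3 counts over the group. Intervals and floors cover counting error only, because reads amplified by PCR without molecular identifiers are not independent molecules. H2-Q8 is uncertain, since its estimated counts equaled those of its neighbor H2-Q6 (tolerance 0.1%) in 8 of the 8 in vivo libraries where it was above 0. In the 3 MC38 supernatant libraries they were 33.7, 0 and 0 against 1094, 1251 and 1019 for H2-Q6. The sum of both genes was 197 CPM in TuMon1 and 13.5 CPM in TuMon2. On GRCm38, Fn1 (Entrez Gene ID 14268) spans positions 71585473 to 71653280 of chromosome 1, Cd72 (12517) 43447724 to 43455102 of chromosome 4, Ccl24 (56221) 135569935 to 135573123 of chromosome 5, Sqle (20775) 59315092 to 59331193 of chromosome 15 and Arg1 (11846) 24915207 to 24927470 of chromosome 10, each a protein-coding gene.

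All 43 members of the type I interferon response list were higher in TuMon1. The median log2 difference was 1.14 (camera adjusted p = 7.55e-21, or 0.129 with an estimated correlation). Ifi44 rose by 3.65 ± 0.24 and Isg15 by 1.89 ± 0.28. Cxcl10 (adjusted p = 0.0362) did not always pass (range over the alternatives 2.86e-09 to 0.107). Of 24 interferon gamma linked genes, 23 were higher (median 1.61, camera adjusted p = 5.49e-12; 0.186 with an estimated correlation). They included the immunity-related GTPase Iigp1 (4.05 ± 0.51), the T cell attractant Cxcl9 (2.27 ± 0.30) and the checkpoint ligand Cd274, which encodes PD-L1 (1.39). In the MHC class I list 18 of 19 members rose (camera adjusted p = 4.63e-12, or 0.129 with an estimated correlation). H2-K1 (1.67 ± 0.09) and B2m, the class I light chain (1.29 ± 0.07), were among them. The trimming peptidase Erap1 differed by -0.12 ± 0.08 without passing the test, and passed with only the groups compared in the fit (-0.15, adjusted p = 0.0367, range over the alternatives 0.0367 to 0.414). The division of reads among similar H2 genes is uncertain. All 10 MHC class II list members rose (median 1.48, camera adjusted p = 3.5e-06, or 0.186 with an estimated correlation). H2-Aa stood at 2922 ± 469.1 against 537.7 ± 48.8 CPM, and Ciita, the master regulator of class II genes, rose by 1.47. Adjusted over the list alone, the counts were those over all genes in 207 of 288 pairs of list and comparison, and both are given for the lists named where they differ.

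Signals to T cells also differed. In the list of costimulation, checkpoint and T cell attracting chemokine genes, 17 of 24 members were higher and 3 lower (17 and 4 adjusted over the list alone; camera adjusted p = 0.000654; 0.234 with an estimated correlation). Ccl5 rose by 3.43, Il12b, a subunit of interleukin 12, by 4.52 and the costimulatory receptor Cd40 by 2.03, while the costimulator Cd80 fell by 0.54. Of 25 NF-kappaB inflammatory genes, 10 rose and 3 fell (camera adjusted p = 0.249); Tnf rose by 1.75, and Il1b differed by 0.12 without passing. The alternative activation and tissue repair list went the other way, with 11 of 25 members lower and 3 higher (camera adjusted p = 0.00787, or 0.326 with an estimated correlation). Arg1, the arginase of repair-type macrophages, stood at 251.0 ± 43.5 CPM in TuMon1 and 1544 ± 556 CPM in TuMon2 (-2.62 ± 0.67, adjusted p = 0.00338). F13a1, the clotting factor XIII A chain, fell by 2.72, Mrc1, the mannose receptor, by 1.55 and Chil3 by 1.90, whereas the anti-inflammatory cytokine Il10 rose by 1.5.

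Metabolic genes differed in blocks. Of 30 hypoxia and glycolysis genes 26 were lower in TuMon1 and none higher (median -0.66, camera adjusted p = 2.12e-11; 0.129 with an estimated correlation), with the oxygen sensor Egln3 at -2.31, phosphoglycerate kinase Pgk1 at -1.01 and the glucose transporter Slc2a1 at -1.0. Of 20 cholesterol synthesis and uptake genes 18 were lower and none higher (median -1.33, camera adjusted p = 1.3e-14), and this call held with an estimated correlation (adjusted p = 0.0385). Fdft1, squalene synthase, fell by 1.65 and the sterol regulator Srebf2 by 1.36. The lipid efflux and handling list split, with 9 of 20 members higher and 5 lower (camera adjusted p = 0.204). The cholesterol exporter Abcg1 (1.67), the sterol receptor Nr1h3 (2.18) and the lipid regulator Pparg (2.77) rose, and the desaturase Scd2 fell by 2.22.

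Maturation and proliferation genes moved as well. In the macrophage list 16 of 30 members were higher and 4 lower (16 and 5 adjusted over the list alone; camera adjusted p = 0.011; 0.395 with an estimated correlation). The complement gene C1qa (2.80 ± 0.65) and the receptor kinase Axl (1.72) were among those higher. In the classical monocyte list 13 of 20 members were lower and 1 higher (camera adjusted p = 7.59e-07, or 0.129 with an estimated correlation). Of 15 nonclassical monocyte genes 9 fell and 3 rose (camera adjusted p = 0.0623, and adjusted p = 0.0358 with the replicate block, range over the alternatives 0.00457 to 0.233). The 30 cell cycle genes were all higher in TuMon1 (median 1.5, camera adjusted p = 1.29e-11; 0.186 with an estimated correlation). Topoisomerase Top2a rose by 2.32 and the proliferation marker Mki67 by 1.19 ± 0.33. Of 19 immediate early and heat shock genes 3 rose and 6 fell (camera adjusted p = 0.264), and of 18 endoplasmic reticulum stress genes 4 rose and 5 fell (camera adjusted p = 0.735, pointing down while the median was 0.06).

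Markers of other cells differed beside these groups. In TuMon1, 9 of 14 T and NK cell genes were higher and 1 lower (camera adjusted p = 0.0048; 0.129 with an estimated correlation). Their levels were low, such as 3.33 CPM of Gzmb against 0.246 CPM, and 3.38 CPM of Cd4 against 0.0572 CPM (log2 difference 5.58, and 9.04 without TuMon2 replicate 4). Of 16 dendritic cell genes 8 were higher and 1 lower (camera adjusted p = 0.00917, or 0.186 with an estimated correlation), among them Ccr7 (2.92) and Clec9a (3.74). Neutrophil genes were lower in TuMon1 for 9 of 17 members and higher for 2 (camera adjusted p = 0.0062; 0.357 with an estimated correlation), with Mmp8 at -1.98. Epithelial genes were lower for 7 of 10 and higher for 2 (camera adjusted p = 0.0325; 0.224 with an estimated correlation). Without the foreign-RNA libraries this became 0.0606 (range over the alternatives 8.83e-05 to 0.224). Cdh1, which encodes E-cadherin, was at 6.64 against 47.5 CPM. Fibroblast and endothelial genes (5 of 18 higher, 1 lower, or 4 and 1 adjusted over the list alone, camera adjusted p = 0.198) passed only without the foreign-RNA libraries (adjusted p = 0.0235, range over the alternatives 0.0235 to 0.731). B cell genes (4 of 8 higher, 1 lower, camera adjusted p = 0.204) passed no camera test. Nor did red cell genes (2 of 5 higher) and granulocyte genes of the eosinophil, basophil and mast cell list (1 of 6 higher, 0 adjusted over the list alone).

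**Figure D3:**
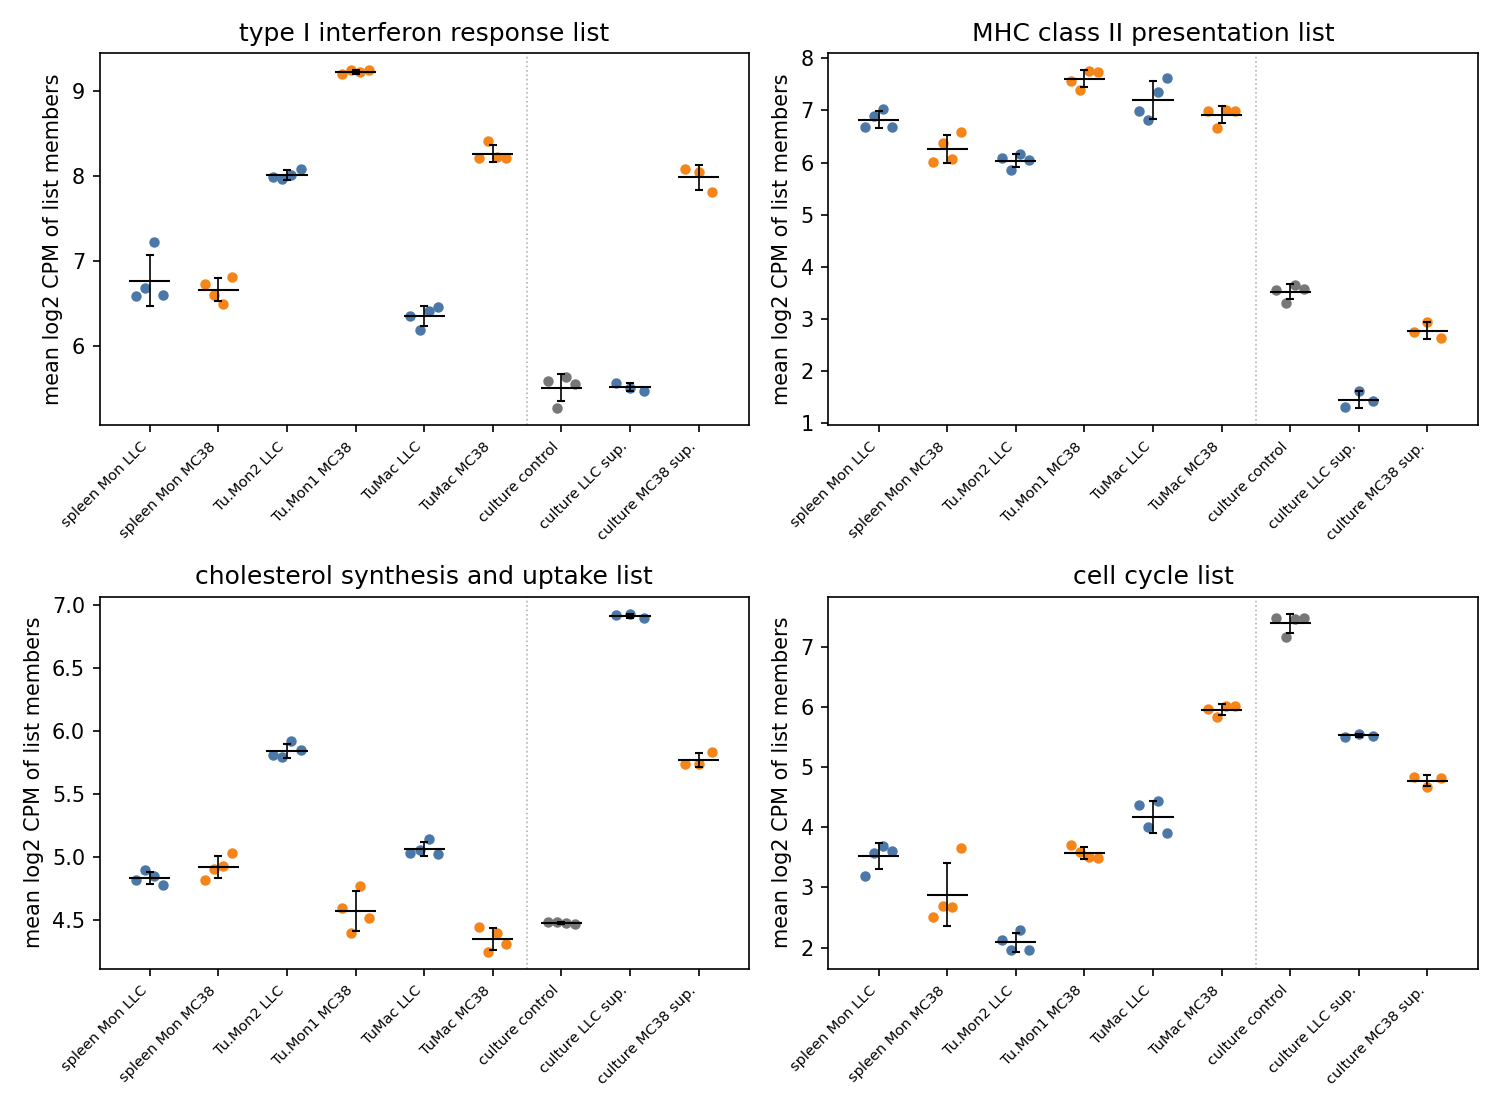
Mean log2 CPM of list members in each library (points) with group means and SD, for the type I interferon, MHC class II, cholesterol and cell cycle lists. TuMon1 lies above TuMon2 for the interferon, MHC class II and cell cycle lists (median log2 differences of 1.14, 1.48 and 1.5) and below it for the cholesterol list (-1.33).

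Bone marrow monocytes cultured with supernatant let MC38 be compared with LLC supernatant in the absence of a tumor. Interferon response and class I genes were again higher on the MC38 side and cholesterol genes lower, while cell cycle genes were lower. Irf7 stood at 1328 ± 120.6 CPM after MC38 and 83.6 ± 3.20 CPM after LLC supernatant (SD, n = 3 each; log2 difference 3.99 ± 0.12, adjusted p = 2.16e-08), and control cells had 111.0 ± 14.1 CPM (n = 4). The monocyte chemoattractant Ccl8 was at 673.3 ± 60.3 against 2.02 ± 0.314 CPM (8.37 ± 0.17), and Mki67 at 105.5 ± 20.5 against 370.8 ± 23.7 CPM (-1.81 ± 0.14, adjusted p = 7.45e-06). Of 12603 genes tested, 2723 were higher and 2332 lower after MC38 supernatant, 1221 of them beyond 2-fold. The majority turned with the scaling, from 53.9% higher to 46.2% with RLE and with upper quartile factors and 46.1% with DESeq2. The total of 5055 became 7424 without the foreign-RNA libraries, which leaves 2 libraries after MC38 supernatant.

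The largest rises after MC38 supernatant included Spon1, at 0 counts after LLC supernatant and at least 959-fold higher, Lipg (8.13), complement factor Cfb (7.54), the receptor gene Flt1 (7.30) and Ifit1bl1 (7.28). Apol9b was at least 603-fold higher, but it shares reads with its near-identical copy Apol9a and is uncertain. Serpinb10 (-4.99), Mmp9 (-4.20 ± 0.21), the ion pump regulator Fxyd2 (-4.07), the ficolin Fcna (-3.99) and Serpinb2 (-3.78) were among the largest falls. Thy1 (ratio of 1780, counting interval 320 to 70500), Apod (ratio of 638, interval 218 to 3100) and Col1a2 (9.68 ± 3.10) also ranked high, with Col1a1 at 999 CPM in MC38 supernatant replicate 3. Without that library the Col1a2 difference was 0.98 and did not pass (adjusted p = 0.446, range over the alternatives 0.0181 to 0.446). Thy1 was then at 2.85 (adjusted p = 0.0453) and Apod at 5.6, from 10.23 and 9.07 with it. The adjusted p of Thy1 was 0.121, 0.103 and 0.102 without LLC supernatant replicate 1, 2 or 3 (range over the alternatives 0.0142 to 0.137), and that of Col1a2 was 0.102, 0.12 and 0.12.

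All 43 type I interferon genes were higher after MC38 supernatant (median 2.28, camera adjusted p = 2.12e-31, or 0.182 with an estimated correlation). Ifi44 rose by 5.63 ± 0.24, Isg15 by 3.55 ± 0.13 and the chemokine Cxcl10 by 3.69 ± 0.26. Of 24 interferon gamma linked genes 19 rose and none fell (camera adjusted p = 2.4e-11; 0.157 with an estimated correlation). Iigp1 rose by 6.20 ± 0.38 and Cd274 by 0.93, and Cxcl9 was at -0.67 ± 0.69 without passing. The 19 MHC class I members all rose (median 1.34, camera adjusted p = 1.44e-13; 0.182 with an estimated correlation). H2-K1 rose by 1.56 and Tap1, the peptide transporter, by 1.66. For MHC class II, 7 of 10 rose and 1 fell (camera adjusted p = 0.0032, or 0.284 with an estimated correlation). H2-Aa was low, at 15.56 CPM after MC38 supernatant, 2.14 CPM after LLC supernatant and 14.07 CPM in control cells. In the costimulation and chemokine list 14 of 21 rose and 2 fell (14 and 3 adjusted over the list alone; camera adjusted p = 0.000778; 0.389 with an estimated correlation). Tnfsf10, which encodes TRAIL, rose by 2.57 and Cd40 fell by 0.66. Of 23 NF-kappaB genes 9 rose and 2 fell (9 and 4 adjusted over the list alone; camera adjusted p = 0.181), including Il1b (2.35) and Ccl2 (1.38).

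Cholesterol genes fell without exception, 20 of 20 after MC38 relative to LLC supernatant (median -1.05, camera adjusted p = 1.03e-14; 0.00207 with an estimated correlation). Sqle was at -1.21 ± 0.07 and the sterol carrier Stard4 at -1.90. Of 30 hypoxia and glycolysis genes 16 fell and 1 rose (median -0.35, camera adjusted p = 3.46e-06, or 0.182 with an estimated correlation), with Egln3 at -1.62. The lipid handling list had 5 of 20 higher and 8 lower (camera adjusted p = 0.384). Cell cycle genes were lower for 25 of 30 members and higher for 1 (26 and 1 adjusted over the list alone; median -0.80, camera adjusted p = 7.02e-11; 0.284 with an estimated correlation), opposite to the direction in vivo. The alternative activation list was mixed (6 of 22 higher, 4 lower, camera adjusted p = 0.603). F13a1 fell by 2.27, Il4ra, the interleukin 4 receptor, rose by 1.52, and Arg1 was at 2562 ± 228.7 against 1409 ± 39.8 CPM (0.86 ± 0.22, adjusted p = 0.0126). Leaving out LLC supernatant replicate 1, 2 or 3 moved the adjusted p of Arg1 to 0.0581, 0.0574 and 0.0652, with 0.0757 under DESeq2 and a range over the alternatives of 4.29e-05 to 0.0757. Fn1 went from 1.67 ± 0.93 (adjusted p = 0.195) to -0.64 (adjusted p = 8.49e-05) without MC38 supernatant replicate 3.

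Among lineage lists in culture, 12 of 30 macrophage genes rose and 7 fell (camera adjusted p = 0.484), with Axl up by 4.33 ± 0.15 and Gpnmb at -1.14. Of 20 classical monocyte genes 9 rose and 7 fell (camera adjusted p = 0.384), with Plac8 up by 5.98 ± 0.13 and Lyz1 at -2.54. Of 15 nonclassical genes 8 rose and 1 fell (camera adjusted p = 0.0138; 0.237 with an estimated correlation). Neutrophil genes were higher for 12 of 17 members and lower for 1 (13 and 1 adjusted over the list alone; median 2.95, camera adjusted p = 0.000106, or 0.321 with an estimated correlation). Fibroblast and endothelial genes were higher for 7 of 13 (11 adjusted over the list alone; camera adjusted p = 0.0357; 0.498 with an estimated correlation), in a group where replicate 3 held connective tissue transcripts. Of 4 B cell genes 2 were lower (4 adjusted over the list alone; camera adjusted p = 0.0156; 0.182 with an estimated correlation). Both calls ended without the foreign-RNA libraries. The adjusted p was then 0.105 for fibroblast genes (range over the alternatives 0.015 to 0.498) and 0.0804 for B cell genes (8.07e-05 to 0.182). The median and mean of the endoplasmic reticulum stress list were 0.17 and 0.06 while its camera test pointed down (2 of 18 higher, 2 lower, adjusted p = 0.974).

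Across 12294 genes tested both in tumors and in culture, 1202 were higher on the MC38 side in both (725 expected of independent lists) and 915 lower in both (536 expected), while 499 and 379 were called in opposite directions (616 and 631 expected). The log2 differences correlated across genes with Pearson r = 0.275 and Spearman rho = 0.229, where genes are not independent replicates. All 43 type I interferon genes and 18 of 19 MHC class I genes were higher in both settings, 18 of 20 cholesterol genes were lower in both, and 25 of 30 cell cycle genes were higher in tumors and lower in culture. Without the interferon list members 2055 genes shared a direction, and r was 0.261.

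**Figure D4:**
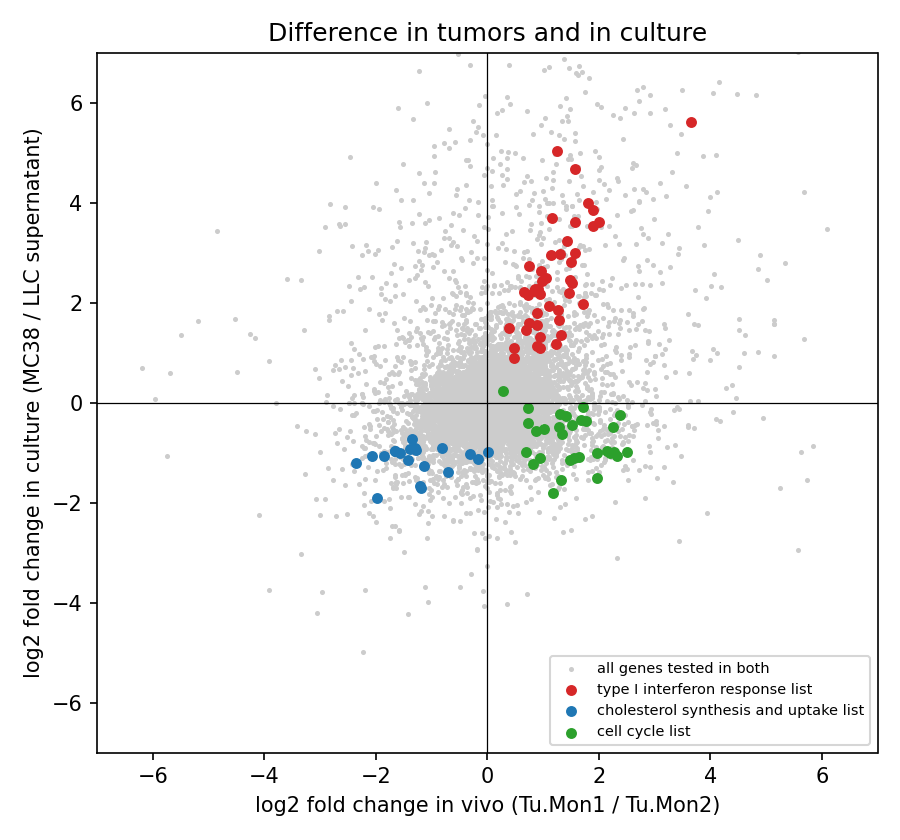
Log2 fold change of each gene between TuMon1 and TuMon2 in tumors (x axis) and between MC38 and LLC supernatant in culture (y axis), with members of fixed lists in color. Type I interferon genes lie in the upper right (43 of 43 higher in both) and 18 of 20 cholesterol genes in the lower left, and 49 of the 12294 genes lie outside the axes.

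Each supernatant was set against control culture to see what the tumor cells' medium changes. Both raised macrophage genes and lowered the cell cycle and neutrophil lists. After MC38 supernatant Spp1, which encodes osteopontin, stood at 11400 ± 590.2 CPM (n = 3) and after LLC supernatant at 14850 ± 158.8 CPM (n = 3), against 9.17 ± 1.45 CPM in control cells (n = 4; log2 differences 10.28 and 10.66). Arg1 rose by 11.79 and 10.93 from 0.787 ± 0.599 CPM, and the myeloperoxidase gene Mpo changed by -8.39 and -11.08. MC38 supernatant changed 8552 of 12603 genes (4460 higher, 4092 lower, or 4280 and 4340 with upper quartile scaling) and LLC supernatant 8615 (4068 higher, 4547 lower, or 4746 and 4039 with only its groups in the fit), and these totals became 9730 and 10133 without the foreign-RNA libraries.

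With MC38 supernatant 29 of 30 macrophage list members rose and none fell (median 5.55, camera adjusted p = 1.59e-13, or 0.00671 with an estimated correlation). The complement genes C1qa (11.40 ± 0.18), C1qb (11.41) and C1qc (11.67) led the list. Ccl8 (12.90), Ccl7 (12.59) and Pf4 (11.71) were among the largest rises overall. LLC supernatant raised 26 of 30 and lowered 2 (median 5.32, camera adjusted p = 2.42e-11; 0.00517 with an estimated correlation). Gpnmb rose by 11.21 and the vitamin K dependent ligand Gas6 by 11.76. Cell cycle genes fell in both, 29 of 30 each, with medians of -2.80 and -1.98 (camera adjusted p = 8.43e-14 and 7.06e-11; 0.308 and 0.291 with an estimated correlation). Classical monocyte genes fell for 17 and 15 of 20 members and rose for 2 and 5 (camera adjusted p = 9.16e-06 and 0.000377, or 0.361 and 0.456 with an estimated correlation). Chil3 fell by 5.11 and 7.4. Ear2 was at least 1290-fold lower after MC38 and at least 1350-fold lower after LLC supernatant, and shares reads with other members of its ribonuclease family. Neutrophil genes were lower for 12 and 14 of 17 and higher for 3 and 2 (camera adjusted p = 0.00269 and 0.000229; 0.389 and 0.348 with an estimated correlation).

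Cholesterol genes rose with both supernatants, 19 of 20 after MC38 (median 1.13, camera adjusted p = 1.72e-06; 0.0168 with an estimated correlation). After LLC supernatant 20 of 20 rose (median 2.26, camera adjusted p = 5.08e-11, or 0.00517 with an estimated correlation). Sqle rose by 2.80 and 4.01. Hypoxia and glycolysis genes rose for 27 and 28 of 30 and fell for 3 and 1 (camera adjusted p = 1.46e-07 and 5.08e-11; 0.104 and 0.044 with an estimated correlation). The lipid handling list rose for 17 of 20 members and fell for 2 in each (camera adjusted p = 5.8e-06 and 2.42e-06; 0.0719 and 0.044 with an estimated correlation). For the type I interferon list the counts were 41 of 43 higher and 1 lower after MC38 (median 2.01, camera adjusted p = 8.43e-14, or 0.34 with an estimated correlation). After LLC they were 20 higher and 15 lower (20 and 16 adjusted over the list alone; median 0.24 and mean below 0, camera adjusted p = 0.66). Irf7 was at 3.58 and -0.41 (-0.27 after LLC with only the groups compared in the fit). MHC class II genes fell for 9 of 10 after LLC supernatant (10 adjusted over the list alone; camera adjusted p = 0.00116; 0.29 with an estimated correlation). The list went both ways after MC38 supernatant (2 higher, 5 lower, camera adjusted p = 0.217).

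Of the genes changed by the supernatants, 3351 rose with both (1440 expected of independent lists) and 3432 fell with both (1480 expected). The values were r = 0.833, rho = 0.81 and a covariance of 3.21 across genes. Both comparisons use the same controls: simulated unchanged groups against them gave r = 0.431 (range 0.394 to 0.506 over 20 simulations), a covariance of 0.111 and 0 shared calls. With the controls split into 2 and 2, which can be done in 6 ways, between 2987 and 3025 genes rose and between 3073 and 3140 fell in both, r lay between 0.687 and 0.784 and the covariance between 3.03 and 3.27.

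Tumor and spleen monocytes of mice with the same tumor were compared. Spleen labels name no CD88 gate, so gate and tissue coincide. In both tumors inflammatory, glycolytic and macrophage genes rose and the nonclassical monocyte list fell. In MC38 tumors the inflammasome sensor Nlrp3 stood at 686.3 ± 76.5 against 64.4 ± 6.27 CPM (3.41, adjusted p = 1.31e-17). In LLC tumors Arg1 was at 1544 ± 556 against 2.71 ± 4.14 CPM (9.06 ± 0.92, adjusted p = 6.51e-08), and Fn1 at 11020 ± 1314 against 3973 ± 295.6 CPM (1.47). Fn1 changed by -2.50 in MC38 tumors. In MC38 tumors 4428 genes were higher and 4830 lower (9258 in all; 47.8% higher, and 39.3% to 51.5% over the alternatives), and without the spleen libraries with fat cell transcripts 7333 were called, 222 of them in the opposite direction. MC38 spleen is then a lone library assumed to vary like the other groups. In LLC tumors 3775 were higher and 4488 lower (45.7% higher, and 38.9% with upper quartile scaling), and the total of 8263 became 8701.

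The largest rises in MC38 tumors included Ccl12 (7.54), the epidermal growth factor Areg (7.30, or 11.27 against the 1 MC38 spleen library without fat cell transcripts), Il1a (7.28) and the prostaglandin synthase Ptgs2 (7.07). The largest falls included those of the granule genes Ngp (-11.95), Ltf (-10.77) and Camp (-10.51). In LLC tumors the largest rises included Cxcl3 (9.86), Arg1, Pf4 (8.47), Spp1 (8.09) and Pdpn (7.54), with Ppbp at a ratio of 1360 (counting interval 464 to 6590). Ngp (-12.06), Ltf (-10.44) and Elane (-7.65) fell. The immunoglobulin joining chain gene Jchain was at least 605-fold lower in MC38 and at least 1230-fold lower in LLC tumor monocytes. Neutrophil genes were lower for 13 of 17 in each tumor and higher for 2 and 1 (camera adjusted p = 7.62e-05 and 9.9e-05; 0.215 and 0.188 with an estimated correlation). In LLC tumors 12 of 14 T and NK genes and 7 of 8 B cell genes were lower too (13 and 7 adjusted over the list alone; camera adjusted p = 0.000139 and 0.00121, or 0.0658 and 0.0954 with an estimated correlation). In MC38 tumors 14 of 18 fibroblast and endothelial genes were lower and 3 higher (camera adjusted p = 0.266), beside fat cell transcripts in the spleen group. Without the libraries holding these the direction of that test turned (adjusted p = 0.0018, range over the alternatives 0.0018 to 0.784).

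By list, NF-kappaB genes rose for 23 of 25 members in MC38 and 19 of 25 in LLC tumors and fell for 1 and 3 (medians 4.72 and 3.23, camera adjusted p = 2.55e-08 and 7.9e-07; 0.185 and 0.165 with an estimated correlation). Hypoxia and glycolysis genes rose for 28 and 29 of 30 and fell for 1 in each (camera adjusted p = 3.91e-11 and 2.17e-18; 0.163 and 0.0658 with an estimated correlation). Macrophage genes rose for 26 and 23 of 30 and fell for 4 and 3 (camera adjusted p = 2.12e-07 and 3.22e-07, or 0.163 and 0.0954 with an estimated correlation). Nonclassical monocyte genes fell for 12 and 11 of 15 and rose for 3 and 2 (camera adjusted p = 0.00039 and 0.000387; 0.141 and 0.0658 with an estimated correlation). Immediate early and heat shock genes, which cell isolation can induce, rose for 16 and 15 of 19 and fell for 1 and 0 (17 higher in MC38 adjusted over the list alone; camera adjusted p = 8.39e-06 and 7.35e-07; 0.215 and 0.161 with an estimated correlation). Endoplasmic reticulum stress genes rose for 13 of 18 in each and fell for 4 and 1 (camera adjusted p = 0.0043 and 0.000285, or 0.215 and 0.0972 with an estimated correlation).

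Interferon genes rose in both tumors, 42 of 43 in MC38 and 37 of 43 in LLC with 0 and 1 lower (medians 2.15 and 0.94, camera adjusted p = 4.21e-20 and 7.26e-11; 0.163 and 0.193 with an estimated correlation). Irf7 rose by 3.19 and 1.22. MHC class II genes rose for 8 of 10 members in MC38 (camera adjusted p = 0.00435; 0.369 with an estimated correlation), with H2-Eb1 up by 2.84. They fell for 8 of 10 in LLC tumors (9 adjusted over the list alone; camera adjusted p = 0.0389, or 0.461 with an estimated correlation), with Ciita at -1.78. Cholesterol genes fell for 13 of 20 and rose for 2 in MC38 (camera adjusted p = 0.0349; 0.442 with an estimated correlation). In LLC tumors 18 rose and 2 fell (camera adjusted p = 7.35e-07; 0.0954 with an estimated correlation). Cell cycle genes rose for 19 of 30 and fell for 2 in MC38 (camera adjusted p = 0.00846, or 0.578 with an estimated correlation). In LLC tumors 27 fell and 1 rose (camera adjusted p = 1.96e-06; 0.318 with an estimated correlation). Without the libraries carrying fat cell transcripts the cell cycle list of the MC38 comparison pointed down (camera adjusted p = 0.848).

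Over the genes tested, 2786 rose in both tumors (1270 expected of independent lists) and 3024 fell in both (1640 expected), and 380 and 286 went opposite ways. Across genes r was 0.494 and rho 0.564. The difference between the tumors in the change from spleen to tumor was tested directly and passed for 5661 genes (3142 higher and 2519 lower in MC38), or 3600 without the MC38 spleen libraries with fat cell transcripts. The share higher was 55.5%, and 47.4% with RLE factors, 44.3% with no filter and 44.9% with only its groups in the fit. Markers of other cells differed too. The change was more positive in MC38 for 10 of 14 T and NK genes (median 3.22, camera adjusted p = 7.77e-05, or 0.0679 with an estimated correlation). It was so for 6 of 16 dendritic genes, with 1 more negative (median 1.13, camera adjusted p = 0.0348, or 0.248 with an estimated correlation), and for 4 of 8 B cell genes (median 1.27, camera adjusted p = 0.0853). It was more negative for 13 of 18 fibroblast and endothelial genes and more positive for 2 (median -5.24, camera adjusted p = 0.0094, or 0.607 with an estimated correlation). This test turned without the foreign-RNA libraries (adjusted p = 0.0351, range over the alternatives 0.0118 to 0.607). Of 10 epithelial genes 6 were more negative and 1 more positive (6 and 2 adjusted over the list alone, median -1.69, camera adjusted p = 0.036). The call did not hold with an estimated correlation. It also ended without those libraries, which leaves 1 MC38 spleen library. All 43 interferon genes (median 1.25, camera adjusted p = 5.64e-21; 0.15 with an estimated correlation), 10 of 10 MHC class II genes (median 2.19, camera adjusted p = 1.1e-07, or 0.15 with an estimated correlation) and 29 of 30 cell cycle genes (camera adjusted p = 9.41e-15; 0.15 with an estimated correlation) changed more toward higher values in MC38 tumors. The reverse was seen for 18 of 20 cholesterol genes (median -1.43, camera adjusted p = 3.15e-15; 0.0322 with an estimated correlation).

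Macrophages were compared with monocytes of the same tumor to describe maturation there. In both tumors cell cycle genes were higher and classical monocyte, interferon and glycolysis genes lower in macrophages. In MC38 tumors Mcm6, a replication helicase subunit, stood at 184.7 ± 4.57 against 41.5 ± 4.27 CPM (2.15, adjusted p = 8.1e-13). In LLC tumors Mcm6 was at 83.1 ± 14.3 against 15.6 ± 2.30 CPM (2.42; SD, n = 4 throughout). In MC38 tumors 3274 genes were higher and 3680 lower in macrophages, and in LLC tumors 3859 and 3471. The share of called genes that were higher was 47.1% and 52.6%, 45.1% and 48% with RLE factors, and 58.1% and 66.1% with upper quartile scaling. Mitochondrial transcripts took 2.69 ± 1.63% of counts in MC38 macrophages against 1.07 ± 0.203% in TuMon1, and 3.54 ± 0.788% in LLC macrophages against 1.36 ± 0.125% in TuMon2. The totals of 6954 and 7330 became 7385 and 7782 without the spleen libraries with fat cell transcripts.

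Among the largest rises were the adhesion genes Ptprm (5.31) and Cadm1 (4.02), the collagen gene Col14a1 (4.28) and the resistin-like gene Retnla (4.12) in MC38 macrophages, and Cadm1 (5.51), Cspg4 (4.45) and Fcrls (3.37) in LLC macrophages. Cd177 (-5.14 and -8.92), Chil3 (-5.14 and -5.27) and Slpi (-3.80 and -5.32) fell in both. Cell cycle genes rose for 30 of 30 in MC38 and 28 of 30 in LLC with 0 and 1 lower (medians 2.49 and 2.32, camera adjusted p = 8.13e-20 and 4.57e-13, or 0.25 and 0.277 with an estimated correlation). Classical monocyte genes fell for 20 and 17 of 20 (20 and 18 adjusted over the list alone; camera adjusted p = 8.02e-14 and 1.59e-12; 0.0266 and 0.041 with an estimated correlation). Interferon genes fell for 41 and 42 of 43 (medians -0.94 and -1.60, camera adjusted p = 8.16e-16 and 1.6e-26; 0.372 and 0.153 with an estimated correlation). Hypoxia and glycolysis genes fell for 26 and 27 of 30 (27 and 28 adjusted over the list alone; camera adjusted p = 5.11e-08 and 2.02e-11, or 0.372 and 0.162 with an estimated correlation). NF-kappaB genes fell for 15 and 18 of 25 (camera adjusted p = 0.000259 and 2.79e-05; 0.593 and 0.348 with an estimated correlation). Neutrophil genes were lower for 6 and 13 of 17 and higher for 1 in each (medians -1.11 and -2.56, camera adjusted p = 0.0682 and 7.47e-05, or 0.336 in LLC with an estimated correlation). In MC38 this list passed with the replicate block (adjusted p = 0.0426), without the foreign-RNA libraries (0.0338) and with fry (0.00226; range over the alternatives 0.00226 to 0.6). Macrophage list members rose for 11 of 30 and fell for 3 in MC38 (camera adjusted p = 0.0837), passing without the foreign-RNA libraries (adjusted p = 0.0312) and with fry (0.0185; range over the alternatives 0.0185 to 0.6). In LLC 17 rose and 3 fell (camera adjusted p = 0.00854; 0.465 with an estimated correlation). MHC class II genes fell for 8 of 10 in MC38 (camera adjusted p = 0.0191, or 0.6 with an estimated correlation). In LLC macrophages 7 of 10 rose (camera adjusted p = 0.00069; 0.348 with an estimated correlation). Ciita was at -1.33 in MC38 and H2-Eb1 at 2.12 in LLC. Dendritic cell genes had 2 of 16 higher and 3 lower in MC38 and 5 higher and 2 lower in LLC (medians -0.27 and 0.85, camera adjusted p = 0.794 and 0.275).

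Macrophages of MC38 tumors were compared with those of LLC tumors, a contrast whose labels involve no Sca1 gate. Interferon, class I and cell cycle genes were higher in MC38 macrophages and Fn1 and cholesterol genes lower, as between the monocyte groups. Irf7 stood at 1320 ± 109.8 against 309.4 ± 33.3 CPM (SD, n = 4 each; 2.09, adjusted p = 3.66e-13), the nitric oxide synthase Nos2 at 57.6 ± 7.03 against 3.40 ± 1.70 CPM (4.07), and Fn1 at 264.5 ± 45.2 against 10560 ± 751.6 CPM (-5.32 ± 0.13, adjusted p = 2.71e-19). There were 2962 genes higher and 3018 lower in MC38 macrophages (49.5% higher, and 48.1% to 50.9% over the alternatives), 5980 in all, and 6630 without the spleen libraries with fat cell transcripts. The largest rises included Fcrl5 (7.05), Lipg (5.38) and Fgl2 (4.33), next to H2-Q8 (at least 1590-fold, uncertain as above), and Fam20a (-5.01), the lipoxygenase Alox5 (-4.67) and Cdh1 (-4.01) fell with Fn1.

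All 43 interferon genes were higher in MC38 macrophages (median 1.84, camera adjusted p = 1.76e-34; 0.151 with an estimated correlation). So were 23 of 24 interferon gamma linked genes (camera adjusted p = 1.78e-16, or 0.151 with an estimated correlation). The same held for 19 of 19 MHC class I genes (camera adjusted p = 6.68e-14; 0.151 with an estimated correlation) and 30 of 30 cell cycle genes (median 1.81, camera adjusted p = 3.33e-16; 0.177 with an estimated correlation). Markers of other cells were also higher, 7 of 14 T and NK genes with 1 lower (8 and 1 adjusted over the list alone; median 1.56, camera adjusted p = 0.104, and adjusted p = 0.00017 with fry, range over the alternatives 0.00017 to 0.367) and 6 of 18 fibroblast and endothelial genes (median 1.16, camera adjusted p = 0.0767). The latter list passed without the foreign-RNA libraries (adjusted p = 0.00481, range over the alternatives 0.00481 to 0.725). In the costimulation and chemokine list 15 of 24 rose and 3 fell (16 and 3 adjusted over the list alone; camera adjusted p = 1.65e-05, or 0.244 with an estimated correlation). Cholesterol genes fell for 17 of 20 and rose for 1 (18 and 1 adjusted over the list alone; camera adjusted p = 5.91e-07; 0.151 with an estimated correlation). Hypoxia genes fell for 20 of 30 and rose for 1 (camera adjusted p = 1.05e-05, or 0.293 with an estimated correlation). MHC class II genes had 2 of 10 lower and none higher (median -0.05, camera adjusted p = 0.367). Cd74 was at -0.27 (adjusted p = 0.134), which became -0.39 (adjusted p = 0.0329) without LLC macrophage replicate 2, range over the alternatives 0.0329 to 0.571.

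The difference between tumor lines was then tested for being unequal in macrophages and monocytes, which held for 1916 genes (825 with a more positive and 1091 with a more negative MC38 difference in macrophages), or 2461 without the spleen libraries with fat cell transcripts. The share more positive was 43.1%, and 49.4% with RLE factors, 35.3% with upper quartile factors, 51.6% with the stricter filter and 51.7% without TuMon2 replicate 1. It was 51.4% and 50.6% without TuMon2 replicate 3 or 4 and 50.8% without TuMon1 replicate 4. Among interferon genes 27 of 43 had a larger MC38 excess in macrophages (34 adjusted over the list alone; camera adjusted p = 3.63e-22; 0.155 with an estimated correlation). For 8 of 10 MHC class II genes the MC38 excess was smaller in macrophages (10 adjusted over the list alone; camera adjusted p = 3.46e-12; 0.0941 with an estimated correlation), with H2-Eb1 at -2.74. So it was for 5 of 16 dendritic genes, with 1 larger (9 and 1 adjusted over the list alone; median -1.16, camera adjusted p = 0.0376, or 0.394 with an estimated correlation). Of 14 T and NK genes 2 had a smaller excess (median -0.82, camera adjusted p = 0.0724). That list passed with the replicate block (adjusted p = 0.0475), without the foreign-RNA libraries (0.0266) and with fry (0.00713; range over the alternatives 0.00713 to 0.399). Neutrophil genes had a more positive difference in macrophages for 3 of 17 members (median 1.65, camera adjusted p = 0.000173; 0.394 with an estimated correlation), and the costimulation list for 4 of 24 with 4 more negative (6 and 4 adjusted over the list alone; median 0.23, camera adjusted p = 0.0456, and adjusted p = 0.0528 with RLE factors, range over the alternatives 0.0266 to 0.59). For 12 of 20 cholesterol genes the MC38 deficit was smaller (13 adjusted over the list alone; camera adjusted p = 3.59e-10, or 0.0941 with an estimated correlation).

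Spleen monocytes of mice with MC38 tumors were compared with those of mice with LLC tumors, the background outside the tumor. The largest differences were transcripts of fat cells in MC38 spleen libraries 1 to 3. The carbonic anhydrase Car3 stood at 2401 ± 1872 against 0.313 ± 0.445 CPM (SD, n = 4 each) and the adipokine Cfd at 1180 ± 829.2 against 0.145 ± 0.291 CPM. Of 3755 genes called, 1903 were higher and 1852 lower with MC38, and 1378 and 142 beyond 2-fold (50.7% of all higher, and 62.1% with RLE, 66.8% with upper quartile scaling, 72% with no filter and 46.4% with the stricter filter). Without the 3 libraries 22 genes passed, 6 higher and 16 lower (27.3% higher), 15 of them among the 3755 in the same direction, with 1205 at an unadjusted p under 0.05. The MC38 group is then a lone library assumed to vary like the others. Without MC38 spleen replicate 4 the count was 6640.

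The type I interferon list had 0 of 43 members higher and 2 lower (median -0.14, camera adjusted p = 0.159), against 43 higher in tumor monocytes, and the MHC class I list had 0 of 19 changed (camera adjusted p = 0.955). With all libraries, 13 of 17 neutrophil genes (15 adjusted over the list alone; camera adjusted p = 7.36e-05; 0.429 with an estimated correlation) were lower with MC38. So were 11 of 20 classical monocyte genes (13 adjusted over the list alone; camera adjusted p = 0.000189; 0.414 with an estimated correlation) and 17 of 30 cell cycle genes (22 adjusted over the list alone; camera adjusted p = 7.23e-06, or 0.525 with an estimated correlation). MHC class II genes were lower for 7 of 10 (camera adjusted p = 0.00226; 0.525 with an estimated correlation). The acute phase gene Saa3 was at 1.70 ± 0.491 against 13.6 ± 3.37 CPM (-3.02, adjusted p = 2.2e-07) and kept its call without the libraries with fat cell transcripts. Ccr2 (-0.81) became -0.55 (adjusted p = 0.183, range over the alternatives 1.24e-09 to 0.183). Of 18 fibroblast and endothelial genes 17 were higher (camera adjusted p = 2.56e-11; 0.414 with an estimated correlation), in the group with fat cell transcripts. Without the libraries holding these, which leaves 1 MC38 library, the calls of these lists ended. The adjusted p became 0.235 for neutrophil genes (range over the alternatives 3.5e-06 to 0.429), 0.0768 for classical monocyte genes (2.58e-05 to 0.414) and 0.103 for MHC class II genes (0.00055 to 0.525). The direction turned for cell cycle genes (0.126, range 3.15e-07 to 0.525), fibroblast and endothelial genes (0.738, range 6.68e-11 to 0.738) and MHC class I genes (0.000602, range 0.000602 to 0.985).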

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

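The splits of the libraries and the tests of explanations in this part were chosen after the results had been seen, whereas the tests of differences between tumors, and between macrophages and monocytes, were planned. Splits of the same libraries into the same group sizes were counted per comparison, the real one included. In 8 comparisons only the real split called as many genes, arguing against chance, without adjustment over the 8. The real split of TuMon1 against TuMon2 in tumors called 6449 genes and the highest other 0. These values were 8552 and 5601 for MC38 supernatant against control, 8615 and 5680 for LLC supernatant against control, 9258 and 2245 for TuMon1 against spleen, and 8263 and 1 for TuMon2 against spleen. They were 6954 and 0 for macrophages against TuMon1, 7330 and 3 for macrophages against TuMon2, and 5980 and 122 between the macrophage groups, each over 35 splits. The 10 splits of the 6 supernatant libraries are too few for a share under 0.05, with 5055 genes for the real split and 2 for the highest other. For the spleen groups 2 of 35 splits called as many genes as the real 3755, and the highest other called 4079. That split exchanges replicate 4 of both groups and so puts the 3 libraries with fat cell transcripts on one side with an LLC library. The splits say nothing of chance for the tests of differences between differences, because their highest counts keep the tumor line labels of one kind of cell and so hold its tumor line difference. For macrophages against monocytes the real split called 1916 genes, the highest other 5232, and 6 of 100 splits as many as the real one. The 5 others that called as many all kept the labels of one kind of cell. For tumors against spleens the values were 5661 and 4304, and 1 of 100 splits called as many.

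Transcripts of other tissues in 5 libraries are the first pattern to weigh. Summed adipose markers reached 22700 CPM there against at most 702 CPM in the 29 others (5 of the 12 markers also exceed 10 CPM in those others and 3 stand in a fixed list), led by Car3 at up to 5340 CPM, although the label of these spleen cells names a Ly6C gate that fat cells would not pass. Cells of the sampled tissue or of the same mouse are argued against by the Y-linked transcripts, whose lowest sum in these libraries was 11.9 CPM against at most 0.892 CPM in the others, and one common source by the ratio of Car3 to Y-linked CPM, which was 151 at its highest and 0.00341 at its lowest. RNA of a male source remains a candidate explanation, since 5 of the 5 libraries lie above all others, but the step at which it entered stays open.

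The type I interferon list, higher in MC38 than in LLC tumor monocytes, is the second. Selection of cells by the Sca1 gate, whose gene Ly6a is itself induced by interferon, is argued against as the whole cause, since 43 of the 43 members were also higher in MC38 macrophages, whose labels name no such gate. A difference between the mice that is also present outside the tumor is argued against by the spleen monocytes, in which the list median was -0.138 on the log2 scale, although 3 of those MC38 libraries carry fat cell transcripts. Monocyte subset and tumor line cannot be told apart, because 0 libraries hold Sca1+ monocytes of LLC or Sca1- monocytes of MC38 tumors. A signal from the tumor cells may contribute, as 43 members were also higher after MC38 than after LLC supernatant in culture, but this remains a hypothesis.

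H2-Q8, at 0 counts in 25 libraries and present in both MC38 tumor groups and 1 culture library, is the third. Reads shared with H2-Q6 and divided evenly are argued against as the whole cause, since in 16 in vivo libraries H2-Q8 was at 0 while H2-Q6 had 123.2 to 582.3 counts, and culture had 33.7, 0 and 0 against 1094, 1251 and 1019 in the 3 MC38 supernatant libraries. Equal values in the other 8 in vivo libraries leave open a division of shared reads that differs between libraries, which was not tested. A gene that only the mice with MC38 tumors carry cannot be told apart from one that is not expressed in spleen, where 0 of the 4 MC38 libraries had a count. The sum of both genes still differed between MC38 and LLC, by 3.86 in monocytes and 2.15 in macrophages on the log2 scale, and how much belongs to either gene stays open.

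Single libraries stood apart from the rest of their group in 49 of 350 groups of 4 values, or 14%, where chance alone does so in about 1 in 20. LLC spleen replicate 3 lay above its group for Ly6a (69.99 CPM), Isg15 (121.5 CPM), Cxcl10 (129.9 CPM), Arg1 (8.903 CPM), C1qa (44.02 CPM), Spp1 (19.91 CPM), Ccl8 (0.577 CPM) and Cd72 (26.67 CPM). Its list means on the log2 CPM scale were also the highest for type I interferon (7.22), interferon gamma linked (5.25), costimulation (3.95) and macrophage genes (5.39), and LLC spleen replicate 1 had the lowest neutrophil mean (5.43). MC38 spleen replicate 4, the one library of its group without fat cell transcripts, had the fewest detected genes (14047), the highest Mki67 (73.99 CPM) and the highest means for cell cycle (3.65) and neutrophil genes (5.52), and the lowest for lipid (5.76) and fibroblast genes (-0.73). MC38 spleen replicate 1 was high for Arg1 (8.064 CPM) and Spp1 (15.78 CPM).

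Control culture replicate 2 was low for Ly6c2 (1520 CPM), Irf7 (89.93 CPM) and H2-K1 (451.3 CPM) and for the means of classical monocyte (8.37), cell cycle (7.15) and T and NK genes (-0.17). It was high for lipid (5.095), endoplasmic reticulum stress (6.10), dendritic (2.42) and epithelial genes (2.96), and control replicate 4 was high for Ly6c1 (28.48 CPM). Among tumor monocytes, TuMon2 replicate 2 was low for Ly6a (29.48 CPM) and Cxcl10 (590.5 CPM) and high for Ifi44 (9.723 CPM), and TuMon2 replicate 4 was high for Ccl24 (142.6 CPM). TuMon1 replicate 3 was low for T and NK genes (-0.15), and TuMon1 replicate 1 was high for B cell genes (-0.05). Within the MC38 macrophage group, replicate 3 had the smallest total (15.6 M counts) and the lowest Mmp9 (5.257 CPM), and replicate 4 the highest mitochondrial share (5.12%) and the lowest Ly6a (626.1 CPM). MC38 macrophage replicate 2 was high for the interferon list (8.41) and low for MHC class II (6.67) and C1qa (2717 CPM), and replicate 1 was high for Sqle (13.66 CPM). LLC macrophage replicate 2 was high for Fn1 (11680 CPM) and low for B cell genes (-0.88), and replicate 4 was high for Ccl24 (29.07 CPM).

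The change from spleen to tumor differed between the tumors in the planned test for 5661 genes. It was more positive in MC38 for Slamf7 (4.05, log2), Grap2 (3.88), Kmo (3.63), H2-Eb1 (3.28), Frmd4b (2.49), P2rx4 (1.94), Mcm4 (1.72) and Ms4a4c (1.53). It was more negative for Fn1 (-3.98), Sqle (-2.48), Scd2 (-2.45), Sulf2 (-2.20) and Gramd4 (-1.94). By list, 43 interferon, 10 MHC class II, 18 cholesterol and 29 cell cycle members passed. The difference between tumor lines was unequal in macrophages and monocytes for 1916 genes, among them Vnn3 (3.40), Fgl2 (2.59), Rnf144a (2.56), Siglece (2.47), Spn (1.96), Cmpk2 (1.84) and Idi1 (1.04). On the negative side were H2-Eb1 (-2.74), Lsp1 (-1.92), Lsr (-1.89), Frmd4b (-1.66), Dusp3 (-1.32) and Tesk1 (-1.21), and 27 interferon, 8 MHC class II, 12 cholesterol and 4 cell cycle members passed.

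The comparison of MC38 with LLC supernatant in culture pointed opposite to that of TuMon1 with TuMon2 in tumors for some genes and lists, and the difference between the settings was not tested. The log2 values in culture were 0.86 for Arg1 and -1.81 for Mki67. For lists whose median had opposite signs in tumors and culture, the median in culture was 0.27 for alternative activation, 0.34 for classical monocyte genes, 0.90 for nonclassical monocyte genes, 0.48 for immediate early and heat shock genes, -0.80 for cell cycle, -0.16 for lipid handling, -0.75 for B cell, 2.95 for neutrophil and 1.28 for epithelial genes.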

How the results depend on the processing

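The setting that leaves out the 5 libraries with foreign transcripts was chosen after the results had been seen, and all other settings were planned. Of 482 results on named genes, 437 kept direction and side of the threshold under all settings run on them, 45 changed under at least 1 and 2 of these reversed. Size factors of the RLE method left 481 as they were, upper quartile factors 481, DESeq2 466 of 468 and the stricter filter 469 of 469. The counts of called genes stayed within 1.5 times under RLE and upper quartile scaling, both filters, DESeq2 and the replicate block. Upper quartile scaling moved the median of all genes by over 0.1, from -0.0439 to -0.181 in TuMon1 against spleen, from -0.0152 to 0.0946 in MC38 macrophages against TuMon1 and from 0.0589 to 0.205 in LLC macrophages against TuMon2. The cause of the changes that follow was not tested, unless their construction shows it. The spleen comparison called 3755 genes, 944 with only its groups in the fit, 22 without the 3 libraries with fat cell transcripts, where 1 library stands for MC38, and from 2525 (without MC38 replicate 3) to 6640 (without MC38 replicate 4) with each library left out. The difference between tumors in the change from spleen passed for 3600 genes without those libraries. With an estimated correlation the type I interferon list was not called in vivo (adjusted p = 0.129) or in culture (adjusted p = 0.182), its highest values, and the lowest over its alternatives were 1.71e-22 and 4.89e-34. Fn1 between supernatants lay from -0.64 (without MC38 supernatant replicate 3, which carries connective tissue transcripts) to 2.17 (without replicate 1), and at -0.63 without both foreign-RNA libraries of culture. Lpl, a fat cell gene, went from 5.53 to -0.09 between the spleens without the libraries holding fat cell transcripts. Without these libraries list tests turned direction, with adjusted p = 0.848 for cell cycle and 0.0018 for fibroblast genes in TuMon1 against spleen (over the alternatives 0.00104 to 0.848 and 0.0018 to 0.784). Between the spleens they were 0.000602 for MHC class I (0.000602 to 0.985), 0.126 for cell cycle (3.15e-07 to 0.525), 0.805 for lipid handling (0.00722 to 0.805), 0.0352 for epithelial (0.0352 to 0.824) and 0.738 for fibroblast genes (6.68e-11 to 0.738). For fibroblast genes in the difference between tumors the value was 0.0351 (0.0118 to 0.607). T and NK genes between supernatants turned with fry (adjusted p = 0.0396, over the alternatives 0.0396 to 0.978). The correlations of fold changes kept their sign, and without the foreign-RNA libraries r became 0.248 between tumors and culture and 0.682 between the tumors. Replicates share numbers across groups, but no pair of groups had all same-number correlations over 0.1. A fit with the replicate block called 6445 genes in vivo and 4235 between supernatants, moved no count by over 1.5 times, and changed 7 named genes, all toward no call. It left 282 of 288 list tests as they were, ended 2 calls and made 4. Depth limits genes near the floor, where a count of 0 allows up to 3 counts, and libraries held at least 13047724 counts.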

Other observations

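The tests in this part were planned comparisons, except that the marker genes of other tissues and the setting without the libraries holding foreign transcripts were chosen after these transcripts had been seen. Tumor monocytes of both kinds differed from spleen monocytes in genes of T cell costimulation, tissue repair and dendritic cells. In the costimulation, checkpoint and chemokine list 22 of 24 members rose in MC38 tumors and none fell (camera adjusted p = 8.5e-10, or 0.141 with an estimated correlation). In LLC tumors 18 rose and 1 fell (camera adjusted p = 1.3e-06, or 0.0972 with an estimated correlation). Cd86 rose by 3.14 ± 0.11 (log2 with SE) in MC38 and 2.30 ± 0.11 in LLC tumors, and its partner costimulator Cd80 by 3.50 and 3.76. Of 25 alternative activation and tissue repair genes, 17 rose and 2 fell in LLC tumors (18 and 2 adjusted over the list alone, camera adjusted p = 3.9e-07, or 0.0954 with an estimated correlation), with the mannose receptor Mrc1 at 658.4 ± 146.1 against 12.5 ± 4.83 CPM (SD, n = 4 each). In MC38 tumors 16 rose and 7 fell (camera adjusted p = 0.0141, or 0.369 with an estimated correlation). Dendritic cell genes fell for 12 of 16 members in LLC tumors (1 higher and 12 lower adjusted over the list alone, camera adjusted p = 0.000284, or 0.0954 with an estimated correlation). In MC38 tumors 9 fell and 2 rose (camera adjusted p = 0.019, or 0.215 with an estimated correlation), with the receptor kinase Flt3 at -4.68 in LLC and -4.03 in MC38. Fat cell transcripts stood in 3 of the 4 MC38 spleen libraries, without which the dendritic call in MC38 ended (adjusted p = 0.0571, range over the alternatives 6.85e-10 to 0.215).

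In culture both supernatants raised repair genes, 14 of 22 each, and lowered 6 after MC38 (15 and 7 adjusted over the list alone) and 4 after LLC supernatant (camera adjusted p = 0.0236 and 0.00272, or 0.361 and 0.29 with an estimated correlation). The macrophage elastase Mmp12 went from 0.190 CPM in control cells to 427.7 and 303.0 CPM, and Mrc1 from 14.6 to 1303 and 1907 CPM. Interferon gamma linked genes rose for 19 of 24 members and fell for 4 after MC38 supernatant (camera adjusted p = 0.000212, or 0.308 with an estimated correlation), and went both ways after LLC supernatant (5 higher, 9 lower, camera adjusted p = 0.679). C1qa, at 186.1 ± 30.7 CPM in TuMon2 and 1293 ± 133.3 CPM in TuMon1, was at 1601 ± 135.0 CPM in LLC and 2944 ± 152.4 CPM in MC38 macrophages (SD, n = 4 each). The lipid handling list was higher in MC38 than in LLC macrophages for 10 of 20 members and lower for 3 (camera adjusted p = 0.0415, or 0.285 with an estimated correlation). With the replicate block that list had adjusted p = 0.0701, range over the alternatives 4.85e-06 to 0.285.

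The marker lists of other tissues gave these sums in the 5 libraries with foreign transcripts. Connective tissue markers (8 genes, 8 of them in a fixed list and 2 over 10 CPM elsewhere) reached 4070 CPM against at most 36.9 CPM in the 29 others, led by 999 CPM of Col1a1 in MC38 supernatant replicate 3. That library also held 478 CPM of the imprinted growth gene Igf2 and 290 CPM of H19, and the imprinted genes (5, 0 of them over 10 CPM elsewhere) summed to at most 788 against 3.82 CPM. Glia and neuron markers (8, 1 of them over 10 CPM elsewhere) summed to 467 CPM at most, against 507 CPM in the highest other library, mostly of Mbp, which reached 506 CPM in the 29 others. The astrocyte genes Gfap and Aqp4 were at 275 and 83.7 CPM in MC38 supernatant replicate 3, against at most 0.274 and 0.154 CPM in the 29 others. Epithelial markers (6, all 6 in a fixed list) reached 95.5 against 3.8 CPM. Control culture replicate 2 held 2020 CPM of Msmp, a gene chosen after its value was seen. The labels of these samples name a gate or culture of monocytes.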
